A study of Mus musculus and Homo sapiens with 43 samples.

How the data were processed

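The data were 5 comparison tables that the authors deposited, covering charged tRNA, total tRNA, polysome profiling, RiboTag and translational efficiency. Charged tRNA profiling, polysome profiling, ribosome profiling and RiboTag isolation followed published protocols, and RNA-Seq, polysome and RiboTag libraries were made with the TruSeq RNA kit v2, per the labels' protocols. That kit does not mark strand, so overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name Bowtie2 2.4.1, STAR 2.5.2a, SAMtools, featureCounts, HTSeq and DESeq2 and the build mm10, without saying which was used for which library; mm10 is a mouse build and is listed for the human tRNA libraries too, so the reference of the tRNA probes is not given in the sources used here.

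Per the file headers, 4 tables are DESeq2 results of the authors. The mean normalized count is one value per gene over the libraries of the authors' model. The deposited log2 fold change and its standard error are on the log2 scale, after the authors' normalization by size factors. The deposited Wald statistic is a score, the log2 fold change divided by its standard error, which was checked on the values. The deposited p-values are Wald p-values with an adjusted value; for the polysome table the adjusted p equals a Benjamini-Hochberg adjustment over the genes that have one, and for RiboTag it does not (smallest deposited value 0.121, recomputed over all rows 0.204). The efficiency table is an xtail result per the file headers, with deposited log2 values for mRNA, footprints and their ratio in control (shC) and knockdown (shLars) and no standard error. There the footprint change minus the mRNA change equalled the knockdown ratio minus the control ratio within 7.33e-05, which fixes the direction as knockdown over control. For the other tables the direction is not stated, and values are given by side. None of the tables has a column per library, so counts per library, depth, replicate spread and refits were not analysed here, and the tests planned for counts gave way to the deposited comparisons. The relative size factors were read from mean counts shared by many genes (at least 50 in the RiboTag table and 10 in the polysome table) that were not sums of smaller such values, each taken as 1 read in 1 library; this was done after seeing the data.

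The efficiency table had 9851 rows, of which 18 were left out because a spreadsheet had turned the gene symbol into a date. Of 23495 RiboTag rows, 7 that shared a symbol with a row of higher mean count and 1 without a symbol were left out; all 23495 gene IDs matched the gene name table. Coordinates are from a RefSeq annotation of GRCm38.p6, the assembly behind mm10; 32 of the 33 genes named by size of change or followed by the study were found in it, and 21 of them overlap another annotated gene. Human tRNA probes have no coordinates here. Probes with the prefix m were read as mitochondrial tRNAs.

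A gene passed at an adjusted p under 0.05 as deposited. Named genes were the 10 highest and 10 lowest log2 changes among those that passed, with a mean normalized count of at least 50 where given and no Gm, Rik or pseudogene symbol; a direction with fewer gave all of them, and a comparison with fewer than 5 gave the 5 smallest unadjusted p-values. Lars, Emp3 and Ggt5 were named in each comparison, and up to 2 members per direction of a gene list by smallest p. For tRNA the rule took every leucine probe and the 5 highest and 5 lowest other probes that passed. These rules, 31 gene lists (pathways, and markers of cell types that a tumor could hold), most tests and most alternatives were fixed before the data were examined.

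The 5 cytosolic leucine probes were set against all other probes, mLeu among them, by the difference of medians in an exact permutation test over all subsets of the same size. The charging difference, which takes both tables to have the same numerator, had the root of the summed squared standard errors as its error, which takes charged and total libraries as independent, a normal test and a Benjamini-Hochberg adjustment. Lists with at least 5 tested members were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the Wald statistic, or for efficiency on the signed normal score of the p, with a preset correlation of 0.01 and adjustment over the lists of each comparison. Relations across genes used Spearman's rho with 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Random lists, 10000 per list, were matched in 10 bins of genomic span and 10 of mean count. They were drawn only for lists already seen on the negative side of the polysome comparison.

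The list test, the rank correlation and the tRNA enumeration were tested on simulated data. In 100 simulated sets of 19434 independent normal values with the cytosolic ribosomal protein list shifted by 1 SD, cameraPR called that list in 100. With a shift of 0.5 SD it did so in 71. Unshifted lists had an unadjusted p under 0.05 in 3% and 3.08% of tests. The real polysome statistics had an SD of 1.98, and genes of a list can be correlated. These shares therefore do not show how the test behaves on the real values. The tRNA enumeration gave the p of a brute-force count in 20 of 20 simulated sets. Alternatives were other thresholds, filters on the mean count, the separate xtail estimates, other tRNA summaries and other settings of the list test. Restricting the tRNA test to cytosolic probes and turning the total tRNA table were added after seeing the data.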

Results

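The study followed leucyl-tRNA synthetase (LARS), the enzyme that attaches leucine to its tRNAs, in 43 libraries of several kinds. Charged and total tRNA were profiled in 12 libraries of human lines, 3 of each kind from mcf10a, a non-transformed mammary epithelial line with high LARS, and 3 of each kind from HCC1806, a breast cancer line with low LARS. Polysome profiling of 4T07, a mouse mammary carcinoma line, gave 18 libraries. They came from control cells (shCtrl) and from cells with either of 2 hairpins against Lars (shLars3, shLars4), each as mRNA bound to 1 to 2 ribosomes and to 3 or more, with 3 libraries per group. RNA-Seq of the control and both knockdown lines had 2 libraries per line, and 1 pooled footprint library carried no group label. RiboTag profiling, which isolates mRNA through a tagged ribosomal protein expressed only in cells with Cre, covered 3 PyMT mammary tumors with 1 Lars allele deleted and 3 with both alleles. The values below are the authors' comparison tables. They hold no value per library, so total counts are unknown and no spread between replicates could be computed beyond the deposited standard errors (SE). Mean counts of genes with a single read gave relative size factors of 0.44 to 1.31 for the 6 RiboTag libraries, without showing which library is which. The same reading of the polysome table gave 27 libraries, 9 more than are labelled, with relative size factors of 0.312 to 4.56; genes read once in 9 of the 27 had a log2 change of 0. The polysome mean counts, SE and contrast may therefore rest on libraries not described here. Nothing in the labels says whether the replicates came from separate cultures, so a p-value may measure technical spread only.

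The tRNA comparison asked whether tRNA-Leu differed between the LARS-high and the LARS-low line. Of the 5 cytosolic tRNA-Leu isoacceptors, Leu_CAG differed between the lines in both measurements. In the authors' deposited table, its log2 fold change was -0.73 (SE 0.17, DESeq2 adjusted p = 0.000439) for charged tRNA, a 1.66-fold difference. The authors' deposited table for total tRNA gave -0.89 (SE 0.22, DESeq2 adjusted p = 0.00066) for the same tRNA, a 1.86-fold difference. The remaining isoacceptors did not pass the threshold in the authors' deposited tables, with charged values of -0.48 for Leu_TAA, -0.42 for Leu_AAG, -0.36 for Leu_TAG and 0.27 for Leu_CAA. Total values in the authors' deposited table were -0.87, -0.44, -0.50 and -0.42 in that order, and the mLeu probe stood at 0.17 charged and 0.36 total. Adjusted over the list alone, 2 of the 5 passed for charged and 1 for total tRNA. Which line is the numerator is not stated, so a negative value shows a difference but not which line was lower.

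As a set, the 5 cytosolic leucine probes were not separated from the other probes, which include mLeu. Their median charged value was -0.42 against 0.13 for the 64 other probes with a value (exact permutation test over probes, two-sided, p = 0.0554, adjusted p = 0.166 over 3 tests), and their median total value was -0.50 against 0.03 (exact permutation p = 0.143, adjusted p = 0.215). Taking both tRNA tables to have the same numerator, which neither states, the charging difference, charged minus total, had a median of 0.16 over the 5 leucine probes against 0.01 for the others (exact permutation p = 0.473, adjusted p = 0.473). For Leu_CAG it was 0.16 (SE 0.28, 95% interval -0.39 to 0.71). With the total table turned, the leucine median would be -0.86 against 0.19 (exact permutation p = 0.0532) and Leu_CAG would stand at -1.63 (adjusted p = 1.33e-07), so the charging result depends on that reading. The turned reading would also make charged and total values run against each other over all 69 probes (Spearman rho -0.61). As charged tRNA is part of total tRNA, this argues against the turned reading, although the numerator is stated for neither. Probes are not replicates of the cells. HCC1806 was grown in RPMI and the labels give DMEM for the other cells, so line and medium cannot be separated here.

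Other tRNAs differed between the lines too, some by more than Leu_CAG and some by less. Of 69 probes with an adjusted p, 14 passed for charged tRNA (5 positive, 9 negative), and 13 of 65 passed for total tRNA (8 positive, 5 negative). The highest in the authors' deposited tables was mAsn, at 2.34 (SE 0.71) charged and 2.92 (SE 0.58) total. Asp_GTC stood in the authors' deposited tables at 0.90 (SE 0.14) and 1.08 (SE 0.11), as did Tyr_ATA at 1.20 and 1.61. Trp_CCA at 0.64 and His_GTG at 0.49 passed for charged tRNA in the authors' deposited table, while mAla at 1.19 and Glu_TTC at 0.99 passed for total tRNA. On the negative side, the selenocysteine probe SeC(e)_TCA stood at -1.10 and -1.23 in the authors' deposited tables, mHis at -0.88 and -1.63, Lys_CTT at -0.53 and -0.52, and Gly_TCC at -0.64 and -0.55. Asn_GTT at -0.89, mPro at -0.84 and Thr_TGT at -0.72 passed for charged tRNA only in the authors' deposited table. Across the 69 probes, which are not independent replicates, the charged and total values had a Spearman rho of 0.61, with the same sign in 50; with 1 table turned the rho would be -0.61.

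**Figure D1:**
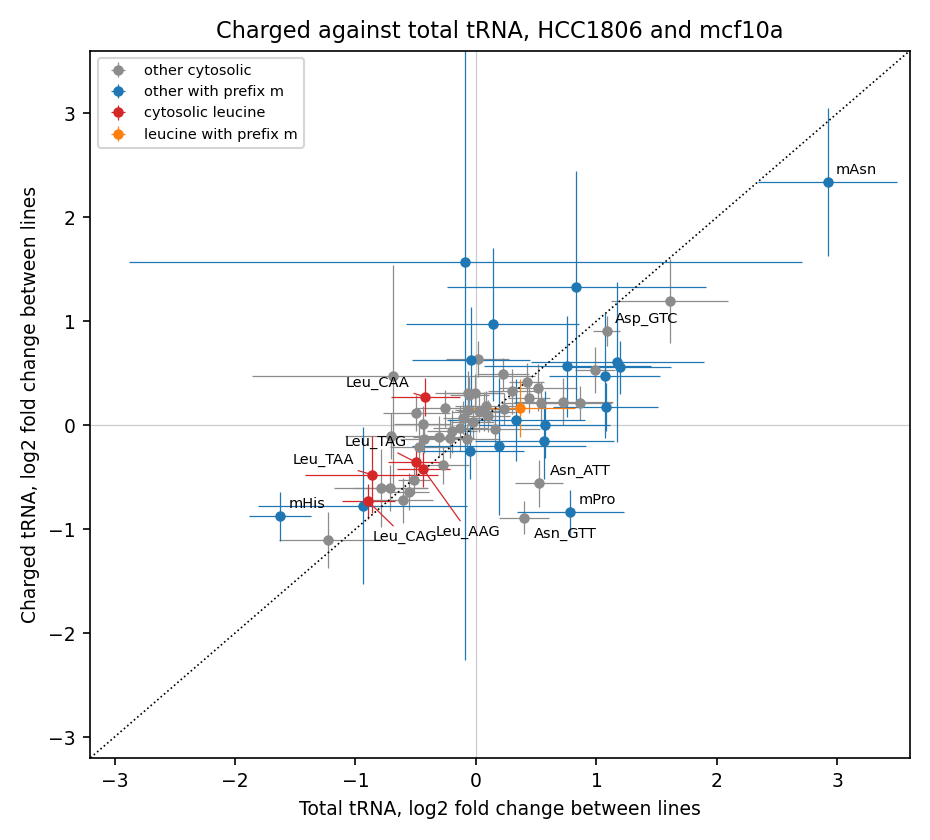
Log2 fold change of charged tRNA (vertical axis) against total tRNA (horizontal axis) between HCC1806 and mcf10a for the 69 probes with both values, from the authors' deposited tables; bars are the deposited SE (1 is longer than the axis), and the dotted line marks equal values. Leu_CAG lies near that line at -0.89 and -0.73, and Asn_GTT, Asn_ATT and mPro lie below it.

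The polysome comparison asked whether LARS depletion moved mRNAs between light and heavy polysomes in 4T07. Of 13485 genes with a deposited adjusted p, 3761 passed (DESeq2 adjusted p under 0.05), 1396 on the positive and 2365 on the negative side. Neither the direction nor the exact contrast (heavy against light, knockdown against control, or the difference of both) is stated for this table, so genes are described by side. On the positive side of the authors' deposited table stood Irs2, an adaptor of the insulin receptor, at a log2 fold change of 5.03 (SE 0.58, adjusted p = 1.02e-15), a 32.6-fold difference. The transcriptional repressor Rest stood at 4.72 (SE 0.39, adjusted p = 1.08e-29) in the authors' deposited table, below the actin-binding Shroom4 at 4.78 and Zbed6, which lies inside Zc3h11a and can share its reads, at 4.99. Msmp at 4.61, H60b at 4.53, Ccdc85c at 4.38, Zbtb38 at 4.15, Sned1 at 4.08 and Nav3 at 4.02 completed the 10 highest in the authors' deposited table. H60b belongs to a gene family with close copies, so its value is uncertain.

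On the negative side, the small nucleolar RNA gene Snord99 stood at -2.71 (SE 0.47, adjusted p = 4.12e-07), Snora24 at -2.49 and Snord65 at -2.41 in the authors' deposited table. All 3 lie inside other genes (Snhg12, Snhg8 and 2410006H16Rik), whose reads they can share, and Snhg8 itself stood at -2.17 in the authors' deposited table. The ribosomal protein genes Rps29 (-2.29), Rpl41 (-2.28) and Rps21 (-2.27) came next in the authors' deposited table, genes whose many processed copies make single values uncertain. Ovol3 (-2.24), the B cell receptor partner Cd72 (-2.23) and the ATP synthase subunit gene Usmg5 (-2.19) closed the 10 lowest in the authors' deposited table; Ovol3 overlaps Polr2i, Cd72 overlaps Tesk1 and Usmg5 overlaps Taf5.

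Lars itself (mm10 chromosome 18, 42202298 to 42262237) stood at -0.82 (SE 0.30, adjusted p = 0.0285) in the authors' deposited polysome table, and its overall mRNA level cannot be read from it. Emp3, a membrane protein that the study is known to have followed (chromosome 7, 45918023 to 45921426), stood at -1.15 (SE 0.26, adjusted p = 0.000127) in the authors' deposited table, a 2.22-fold difference. Its relatives Emp1 and Emp2 stood at 0.62 (adjusted p = 0.069) and -0.27 (adjusted p = 0.21) in the authors' deposited table. Ggt5, a gamma-glutamyltransferase also followed by the study (chromosome 10, 75589327 to 75617200), had a mean normalized count of 0.313 in the authors' deposited table, too low for an adjusted p.

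Among 27 gene lists tested, the machinery of translation and respiration stood apart from other genes. Of 82 cytosolic ribosomal protein genes, 80 passed on the negative side and 0 on the positive side (81 adjusted over the list alone), with a median of -1.42 (limma cameraPR, adjusted p = 2.63e-49); Rpl23a stood at -1.74 and Rps25 at -1.83 in the authors' deposited table. Of 75 nuclear genes of oxidative phosphorylation, 69 passed on the negative side (71 adjusted over the list alone), with a median of -1.38 (cameraPR adjusted p = 3.95e-32), among them Ndufa5 at -1.95 and Uqcrb at -1.63 in the authors' deposited table. Of 78 mitochondrial ribosomal protein genes, 66 passed on the negative side (69 adjusted over the list alone), with a median of -0.99 (cameraPR adjusted p = 2.14e-28), such as Mrps18c at -1.71 and Mrps9 at -0.81 in the authors' deposited table. The median of all tested genes was -0.12.

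Translation factors were divided. Of 45 measured, 17 passed on the negative side, with Eif1 at -1.33 and Eef1b2 at -0.97 in the authors' deposited table, and 3 on the positive side, with the translation inhibitor gene Eif4ebp2 at 1.69 and Eif3a at 0.79 (19 and 3 adjusted over the list alone; cameraPR adjusted p = 0.00852). Of 22 genes of cytosolic aminoacyl-tRNA synthetases and their partners, 5 passed on the negative side, over all genes and adjusted over the list alone, with the scaffold genes Aimp2 at -0.77 and Aimp1 at -0.81 in the authors' deposited table (cameraPR adjusted p = 0.03). Over all genes, 2365 of 13485 passed on the negative side. These last 2 lists lost their call with the log2 change as statistic (cameraPR adjusted p = 0.85 for both). They also lost it with genes of a mean count of at least 10 (cameraPR adjusted p = 0.0928 for translation factors and 0.165 for synthetases). The same held with a preset correlation of 0.05 (cameraPR adjusted p = 0.179 for both), and only ranks kept both calls. An estimated correlation needs values per library and could not be had.

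The other 22 lists did not pass (adjusted p from 0.0982 to 0.98). The lowest of these was branched-chain amino acid breakdown, with 21 of 22 genes negative, 1 past the threshold over all genes and 1 adjusted over the list alone; it passed with ranks of the statistic (cameraPR adjusted p = 0.00417). Of 31 genes of the amino acid response, 2 passed on the positive and 5 on the negative side, the same numbers adjusted over the list alone. In the authors' deposited table Sesn2, a leucine sensor, stood at 1.74 and the leucine transporter gene Slc7a5 at 0.35, while Psph, of serine synthesis, stood at -0.67 and Trib3 at -0.43. Of 28 mesenchymal genes, 5 passed on the positive side and 1 on the negative side (5 and 1 adjusted over the list alone), with Itgb3 at 1.22, Tgfbr1 at 0.97 and S100a4 at -1.68 in the authors' deposited table. Longer genes tended to the positive side: across 13441 genes, the polysome value and the genomic span had a Spearman rho of 0.38 (permutation p = 1e-05, the smallest possible, adjusted p = 1e-05 over 3 comparisons). The rho with genomic span was 0.19 for efficiency (9813 genes) and 0.12 for RiboTag values (13983 genes), with the same permutation p and adjusted p. Genes are not independent replicates.

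**Figure D2:**
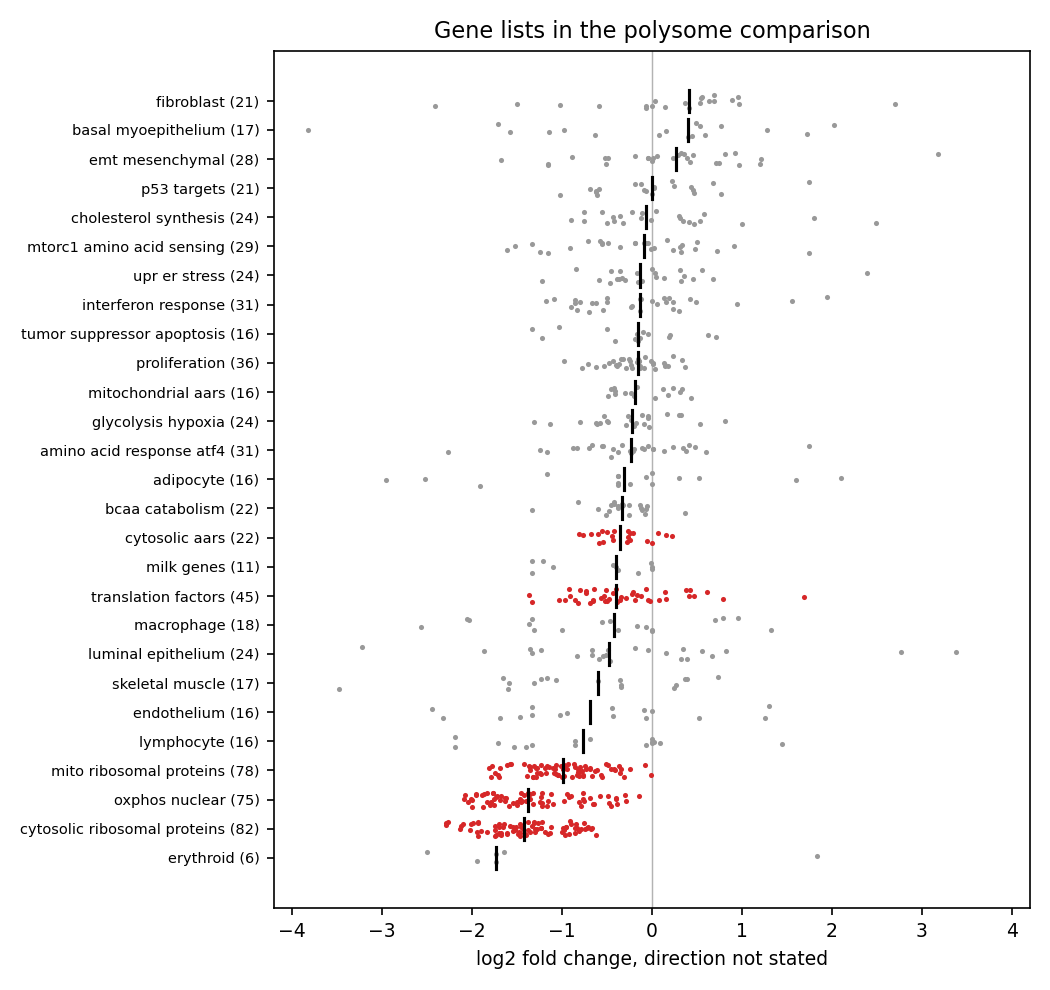
Log2 fold change in the authors' deposited polysome table (horizontal axis, direction not stated) for every measured gene of the 27 tested lists, with the number of genes in brackets; each dot is 1 gene, black bars are medians, and red marks lists with a cameraPR adjusted p under 0.05. The cytosolic ribosomal proteins, oxidative phosphorylation genes and mitochondrial ribosomal proteins have medians of -1.42, -1.38 and -0.99.

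Translational efficiency, the ratio of ribosome footprints to mRNA, was compared between knockdown and control 4T07 cells, and here the table gives the direction. Lars stood at a log2 change of -1.46 in mRNA and -1.23 in footprints in the authors' deposited table, which gives no test of either, and its efficiency stood at 0.23 (xtail adjusted p = 0.939). Of 9833 genes, 5 changed in efficiency and all 5 fell (xtail adjusted p under 0.05). In the authors' deposited table these were Entpd3, an ectonucleotidase gene, at -6.55 (adjusted p = 3.81e-08), the collagen genes Col14a1 at -6.29 (adjusted p = 0.00547) and Col9a1 at -6.06 (adjusted p = 0.0176), the heat shock factor gene Hsf5 at -4.65 (adjusted p = 0.0176) and the keratin gene Krt19 at -2.73 (adjusted p = 0.00582). Their mRNA values in the authors' deposited table lay between 2.09 and 6.09, while their footprint values lay between -1.64 and 0.02. Emp3 stood at 0.37 in mRNA, -0.08 in footprints and -0.42 in efficiency in the authors' deposited table (xtail adjusted p = 0.829). Ggt5 had no value. The first xtail estimate alone, from the fold changes of footprints and mRNA, called 511 genes, 268 positive and 243 negative. The deposited table gives no SE, and with 1 pooled footprint library labelled, the libraries and the number of replicates behind its p-values are unknown.

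Of 21 lists tested on efficiency, 3 lay lower than other genes. All 7 measured fibroblast genes were negative, with a median of -0.54 (cameraPR adjusted p = 0.000152), 0 of them past the threshold over all genes and 2 adjusted over the list alone; Fbln2 stood at -0.99 and Col6a2 at -1.78 in the authors' deposited table. Of 14 luminal epithelial genes, Krt19 was the 1 that passed, over all genes and adjusted over the list alone, and the median was -0.51 (cameraPR adjusted p = 0.000684). Of 36 cytosolic ribosomal protein genes measured, 0 passed in either count, with a median of -0.30 (cameraPR adjusted p = 0.000684) and Rps19 at -0.97 and Rps26 at -0.81 in the authors' deposited table. All 3 kept their call with a correlation of 0.05. Efficiency came without mean counts, so whether these lists rest on genes of low count was not tested. The other 18 lists did not pass (adjusted p from 0.0643 to 0.995), including the cytosolic synthetases, with a median of -0.03 over 22 genes.

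**Figure D3:**
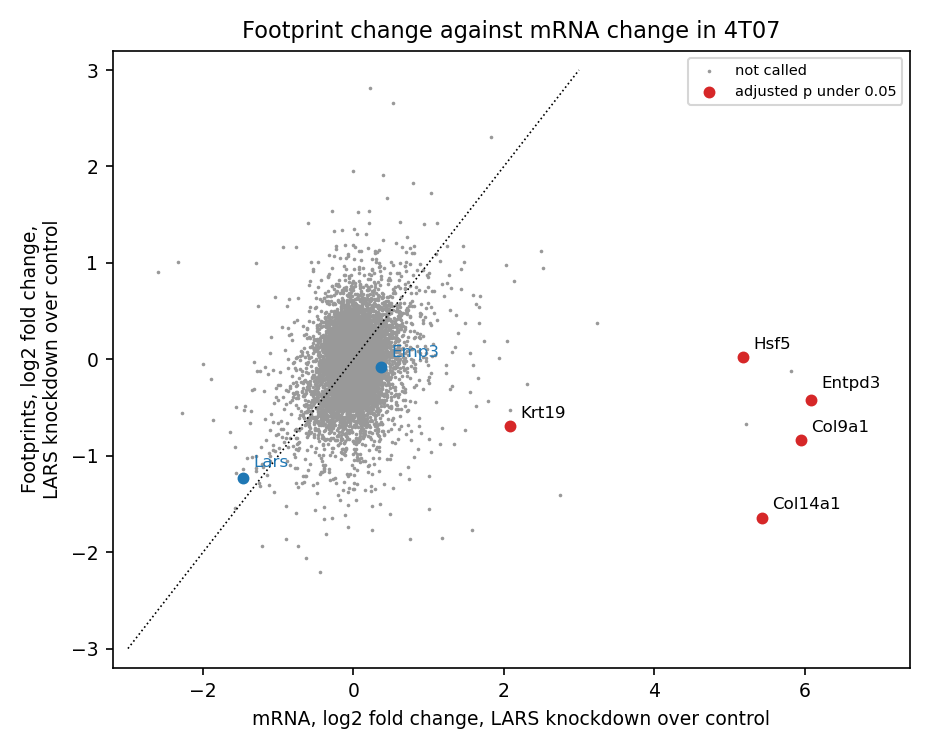
Footprint change against mRNA change, both log2 of LARS knockdown over control in 4T07, for 9833 genes of the authors' deposited table; the dotted line marks equal change. The 5 genes with lower efficiency (red) have mRNA values from 2.09 to 6.09, and Lars (blue) lies near the line at -1.46 and -1.23.

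The RiboTag comparison asked which ribosome-associated mRNAs differed between tumors with 1 Lars allele deleted and tumors with both. No gene passed: of 23487 genes, 0 had a DESeq2 adjusted p under 0.05 in the authors' deposited table, and 280 had an unadjusted p under 0.05 (204 positive, 76 negative). Evenly spread p-values would give about 1174. That number is not a fair expectation here, as genes with a single read were included and the Wald statistic had an SD of 0.65. Lars stood at -0.75 (SE 0.43, unadjusted p = 0.0807) in the authors' deposited table. The direction of this contrast is not stated either. The 5 smallest p-values in the authors' deposited table belonged to Npy, the gene of a neuropeptide, at 2.51 (SE 0.57, adjusted p = 0.121), Sgce at -3.30, the calgranulin gene S100a9 at 3.25, BC002163 at 3.35 and Gsg1l at 2.78. Emp3 stood at 0.88 (SE 0.60) and Ggt5 at 1.39 (SE 0.71, unadjusted p = 0.05) in the authors' deposited table.

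Although no single gene passed, 12 of 27 lists lay apart from other genes, 8 on the positive and 4 on the negative side. A library on the positive side had a relative size factor near 0.44, against 1.07 to 1.31 for the others. Markers of cell types other than luminal epithelium were among them. All 7 erythroid genes were positive, with a median of 2.88 (cameraPR adjusted p = 5.62e-19), 0 past the threshold over all genes and 4 adjusted over the list alone; the globin genes Hbb-bs at 2.79 (SE 0.84), Hba-a1 at 2.96 and Hba-a2 at 2.99 led in the authors' deposited table, and Alas2 stood at 0.00. Basal and myoepithelial genes, 16 of 18 positive, had a median of 0.91 (cameraPR adjusted p = 1.78e-16), with the keratin gene Krt14 at 1.57 (SE 0.62) and the basal regulator Trp63 at 1.55 (SE 0.60) in the authors' deposited table. Fibroblast genes, 19 of 23 positive, had a median of 0.66 (cameraPR adjusted p = 2.74e-07), with Sfrp2 at 1.71 and Col1a1 at 1.03 in the authors' deposited table, and mesenchymal genes, 23 of 30 positive, had a median of 0.50 (cameraPR adjusted p = 3.57e-09). Macrophage genes, 18 of 19 positive, had a median of 0.55 (cameraPR adjusted p = 3.57e-09), with Mrc1 at 1.45 and C1qa at 0.94 in the authors' deposited table. Adipocyte genes (median 0.78, adjusted p = 0.00594), luminal genes (median 0.25, adjusted p = 0.0034) and milk genes (median 0.29, adjusted p = 0.0283) also lay on this side by cameraPR. The milk list lost its call in all 4 other settings tried (adjusted p from 0.0853 to 0.565), and the adipocyte list lost it with genes of a mean count of at least 10 (adjusted p = 0.0566). Outside the erythroid list, 0 members of any of these lists passed in either count.

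On the negative side lay cytosolic ribosomal proteins (median -0.16, 70 of 82 negative, cameraPR adjusted p = 3.84e-05) and proliferation genes (median -0.22, 31 of 36 negative, cameraPR adjusted p = 0.00117), with Ccnb2 at -0.66 (SE 0.48) in the authors' deposited table. Genes of branched-chain amino acid breakdown (median -0.21, adjusted p = 0.026) and mitochondrial ribosomal proteins (median -0.05, adjusted p = 0.0295) also lay there by cameraPR. Endothelial (median -0.13, adjusted p = 0.725), lymphocyte (median -0.03, adjusted p = 0.779) and skeletal muscle genes (median -0.40, adjusted p = 0.184) did not pass. With a correlation of 0.05, the breakdown and mitochondrial ribosomal lists lost their call (adjusted p = 0.114 and 0.299), as they did with genes of a mean count of at least 10 (adjusted p = 0.0766 and 0.0866). With the log2 change in place of the Wald statistic, 3 lists kept it (erythroid, basal and mesenchymal), and the fibroblast and macrophage lists did not (adjusted p = 0.0755 and 0.0687).

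**Figure D4:**
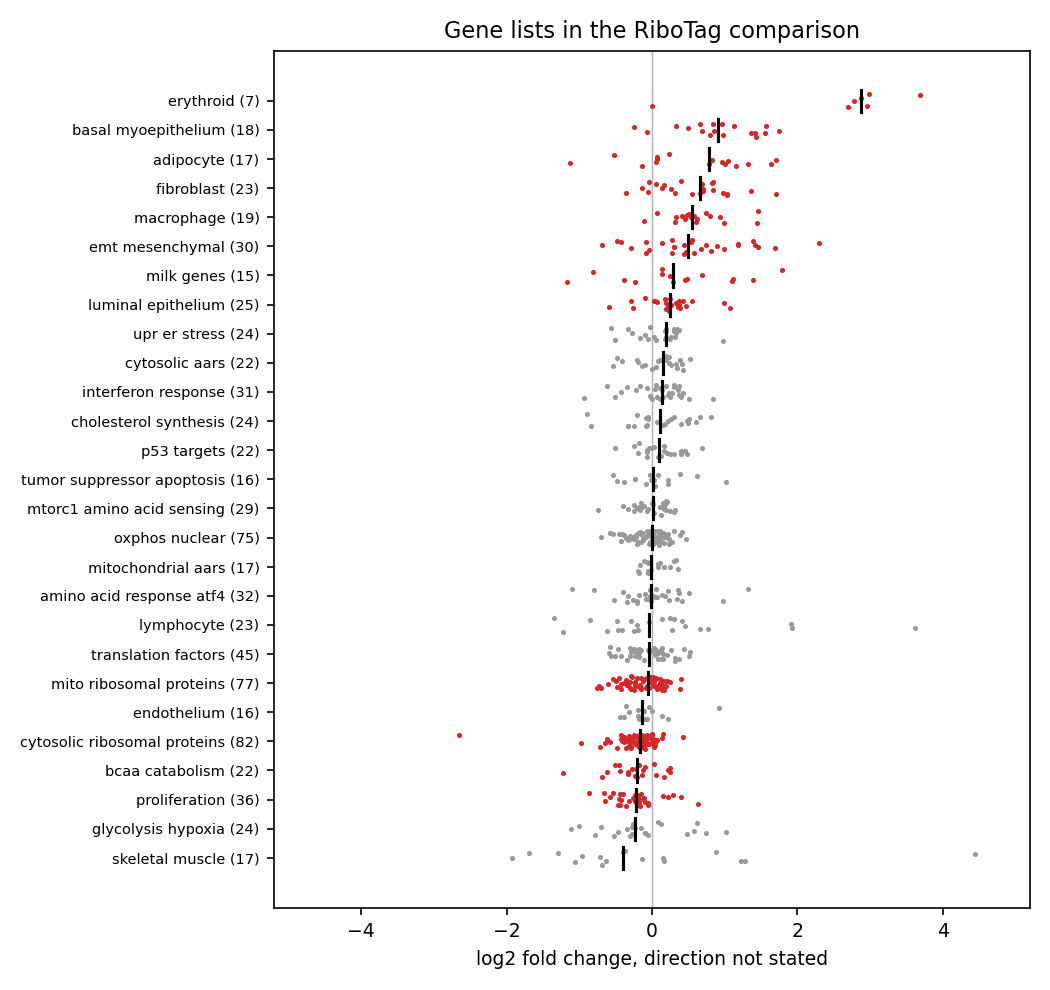
Log2 fold change in the authors' deposited RiboTag table (horizontal axis, direction not stated) for every measured gene of the 27 tested lists, with the number of genes in brackets; each dot is 1 gene, black bars are medians, and red marks lists with a cameraPR adjusted p under 0.05. The erythroid list has the highest median, 2.88, and the endothelial and lymphocyte medians are -0.13 and -0.03.

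Cytosolic ribosomal protein genes had medians of -1.42, -0.30 and -0.16 in the polysome, efficiency and RiboTag values. The direction is known for efficiency alone, so a shared sign across these tables does not show a shared direction. Across all genes, the Spearman rho was 0.05 between polysome and efficiency values (9827 genes, permutation p = 1e-05, adjusted p = 1.5e-05), 0.08 between polysome and RiboTag values (16587 genes, permutation p = 1e-05, adjusted p = 1.5e-05) and -0.04 between efficiency and RiboTag values (9719 genes, permutation p = 4e-05, adjusted p = 4e-05). Signs were the same in 51.2%, 52.3% and 47.4% of genes, and would be in 48.0%, 44.6% and 51.8% if 1 table of each pair were turned. Among the 267 genes with an unadjusted p under 0.05 in both the polysome and efficiency comparisons, rho was 0.35 (permutation p = 1e-05) and 64.0% had the same sign; with the polysome table turned these would be -0.35 and 36.0%. Of the 5 genes with lower efficiency, 0 were among the 1883 negative polysome calls, where 0.959 were expected, too few for the overlap to be tested. Genes are not independent replicates, so these p-values are too small.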

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

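The test of the charging difference was planned, and the values with the total table turned were added after seeing the data. Taking the charged and total tables to have the same numerator, which neither states, 3 of 69 tRNAs passed it (Benjamini-Hochberg adjusted p under 0.05), meaning that the difference between the lines was not the same for charged as for total tRNA. Asn_GTT had a charged minus total log2 value of -1.29 (SE 0.27, adjusted p = 8.5e-05), from -0.89 charged and 0.40 total in the authors' deposited tables. Asn_ATT had -1.08 (SE 0.30, adjusted p = 0.0115), from -0.56 and 0.52 in the authors' deposited tables. The mPro probe had -1.62 (SE 0.49, adjusted p = 0.0236), from -0.84 and 0.78 in the authors' deposited tables. Of the 5 cytosolic leucine probes, 0 passed, and Leu_CAA came closest at 0.69 (SE 0.34, adjusted p = 0.44). With the total table turned, Asn_GTT, Asn_ATT and mPro would stand at -0.49, -0.04 and -0.06 and not pass (adjusted p = 0.142, 0.937 and 0.937), while 20 of 69 probes would pass, 3 of them leucine. No explanation was tested.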

How the results depend on the processing

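The cytosolic-only tRNA setting and the turned total table were chosen after seeing the data; the others were planned. With the total table turned, the leucine charging difference went from 0.16 to -0.86 (exact permutation p = 0.0532), by construction. In all other settings the leucine values kept their sign and had an adjusted p over 0.05; by unadjusted p, the inverse-variance weighted mean of total tRNA, -0.59, lay under 0.05 (exact permutation p = 0.0495, adjusted p = 0.149 over 3 tests), and charged p-values ran from 0.0554 to 0.115. Without mLeu and the other probes with the prefix m, the adjusted p was 0.172 for both charged and total tRNA. Polysome calls went from 3761 to 2493 at an adjusted p under 0.01 and to 1716 with a log2 change of at least 1. Efficiency calls went from 5 to 3 at an adjusted p under 0.01, to 511 with the first xtail estimate (268 positive, 243 negative) and to 8 with the second. Both kept all 5, but for these genes the deposited adjusted p follows the larger of the first and second p-values. That they were kept was therefore fixed in advance. RiboTag calls stayed at 0 in all 5 settings tried. List calls in the polysome comparison went from 5 to 3 with a correlation of 0.05, with the log2 change as statistic, and with genes of mean count of at least 10; ranks gave 6. RiboTag list calls went from 12 to 3 with the log2 change, and to 9, 11 and 8 with a correlation of 0.05, with ranks and with genes of mean count of at least 10. Among genes with an unadjusted p under 0.05 in both comparisons, rho was 0.35 for polysome and efficiency (267 genes, permutation p = 1e-05, from 0.05 over all genes), 0.19 for polysome and RiboTag (37 genes, permutation p = 0.255) and turned to 0.11 for efficiency and RiboTag (11 genes, permutation p = 0.756), where 1 of 11 had the same sign; fewer genes were tested there, and each sign depends on the unstated direction of the polysome or RiboTag table. Otherwise the cause was not tested.

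No paired analysis was possible because the tables have no columns per library. For the same reason leaving out each replicate, the replicate block, TMM, edgeR and DESeq2 refits and other splits of the samples were not run. The mean count filter on efficiency gave no value, as that table has no mean count. The test of CTG leucine codon share and its alternatives were not run, as coding sequences were not used here. Total counts per library are unknown; the deposited SE, where given, sets what each comparison was able to detect, as for Lars in the RiboTag table (SE 0.43 in the authors' deposited table).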

Other observations

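The tests of gene families, of the probes with the prefix m, of efficiency and of RiboTag, and the bound on the SE, were chosen after the results were seen. The test against random lists matched on span and mean count was written down before it was run. It covered only the 3 lists with the smallest polysome list p, whose negative side was already known, and only low medians. Host genes of small nucleolar RNAs named Snhg lay on the negative side of the polysome comparison: 11 of 13 passed there, against 17.5% of other genes (Fisher's exact test, adjusted p = 1.04e-06 over 8 tests), with Snhg1 at -1.65 and Snhg12 at -1.61 in the authors' deposited table. Zinc finger genes named Zfp were seldom on that side, 18 of 318 against 17.8% of other genes (Fisher's exact test, adjusted p = 2.59e-09), and 45 passed on the positive side (adjusted p = 0.063), with Zfp36l2 at 1.46 and Zfp608 at 1.09 in the authors' deposited table. Genes of small nucleolar RNAs (19 of 75 negative, adjusted p = 0.147) and histones (4 of 43 negative, adjusted p = 0.3, median -1.62) did not pass on that side, nor did any of the 4 families on the positive side. Among tRNAs, the 20 probes with the prefix m had a median of 0.47 for total tRNA against -0.07 for the 50 others (permutation p = 0.00286, adjusted p = 0.00429 over 3 tests). For charged tRNA, the 19 of them with a value had a median of 0.17 against 0.08 (permutation p = 0.517). Their charging difference, charged minus total, had a median of -0.28 against 0.10 (permutation p = 0.00185, adjusted p = 0.00429), with 6 of 19 positive, mPro not among these. This takes both tRNA tables to have the same numerator, which neither states; with the total table turned the medians would be 0.58 and -0.07 (permutation p = 0.0193).

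Short genes lay on the negative side of the polysome comparison, and 3 lists of mostly short genes passed there. Genomic span and mean count did not account for these lists as a whole: 0 of 10000 matched random lists had as low a median (1-sided permutation p = 1e-04 for each list, the smallest that 10000 draws can give), and the matched lists had medians of -0.97, -0.56 and -0.45 where the ribosomal, oxidative phosphorylation and mitochondrial ribosomal lists had -1.42, -1.38 and -0.99. Span is not transcript length, which was not tested, and the trend with span also stood in the efficiency (rho 0.19) and RiboTag values (rho 0.12), which have no heavy and light fractions. A contrast of heavy with light fractions, rather than of knockdown with control, may order mRNAs by length. Under assumed default settings with 27 libraries in the model, the SE would reach at most 6.34 for 3 against 3 libraries. The bound would be 4.49 for 6 against 6 and 7.77 for a difference of differences, and the largest SE was 7.77. Such settings would give a bound of 4.08 for 3 against 3 RiboTag libraries, where the largest SE was 4.08. If the settings hold, the largest polysome SE argues against a contrast of heavy with light fractions alone. The settings are not stated, so the contrast is not settled.

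The 5 genes with lower efficiency had mRNA values of 2.09 to 6.09 and footprint values of -1.64 to 0.02 in the authors' deposited table. A candidate explanation is mRNA close to absent in the control, where a ratio is unstable: their mean counts in the polysome table, whose 18 labelled libraries are of the same line, were 2.98 to 40, at or below percentile 2.39 of the genes in the efficiency table, whose median was 815. Their efficiency in the control was extreme, at log2 3.84 to 8.49 (percentile 99.6 or above, against a median of 0.04), and in the knockdown it was 0.57 to 2.81; choosing genes by a large fall favors such values, so this does not tell an unstable control ratio from a real fall. Lower translation of these mRNAs after LARS knockdown stays open as the biological explanation, since 0 of 5 passed in the polysome comparison, where their mean counts are low and the direction is not stated.

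In the RiboTag comparison, the tagged ribosomes should be those of Cre-positive epithelium, yet markers of several other types lay on the positive side. Basal and luminal epithelial genes lay there too. If a lower share of the main cell type raised all others alike, their medians would not differ. The erythroid median was 2.88 against -0.13 for 16 endothelial genes (exact permutation p = 0.000979), and fibroblast and endothelial medians differed too (permutation p = 8e-05). This cannot decide the question, as other types need not rise alike and these pairs were picked after the values were seen. Endothelial genes also had mean counts of at most 76.8, and the p-values permute genes, not tumors. A lower share of luminal cells would put luminal genes on the negative side. They lay on the positive side, 21 of 25, with a median of 0.25 (cameraPR adjusted p = 0.0034). That call was lost with the log2 change as statistic. RNA from blood cells may contribute to the erythroid part, where 7 of 7 genes, 0 of them in another list, were positive and the globins had mean counts of 1559 to 7122 in the authors' deposited table, but the list was taken up for its direction and this decides nothing. 1 library on the positive side had a relative size factor near 0.44, against 1.07 to 1.31 for the others, read from genes with a single read; whether it carries these lists cannot be told apart without values per library. Deletion of 1 Lars allele stays open as the biological explanation, untested.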
